A study of Mus musculus with 8 samples.

How the data were processed

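Total RNA, extracted with Trizol per the labels, from 8 samples of mouse embryoid bodies was measured on 1-colour Affymetrix Mouse430_2 arrays, 4 with retinoic acid alone and 4 with retinoic acid and an Hh agonist. The value table deposited by the authors holds 1 linear intensity per probe set and array. How the authors summarised probes to probe sets, corrected the background and normalized between arrays is not given in the sources used here. The intensities were nearly level between arrays, with medians of 21.6 to 22.6 and 75th percentiles of 56.0 to 58.8, and 62 to 88 probe sets per array were exactly 0. No detection calls were used. Per the file headers, the instrument records give chip lot, fluidics station and the days of hybridisation and scanning. Groups and replicate numbers were taken from the sample titles.

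The authors' normalization was kept. Intensities were turned into log2(intensity + 16), and 64 control probe sets were left out of the tests. A probe set was tested when its mean log2 value over all 8 arrays was above the 40th percentile, an intensity of about 15.1, which left 27022 tested and 18015 untested. Of the 45101 probe sets in the table, 34945 name 1 gene in the platform annotation, 932 name several, 0 are listed without a symbol, 64 are controls and 9160 are not listed. Those naming several genes or not listed were not used for genes. By gene identifier 34741 of the single-gene probe sets matched a RefSeq gene table and by accession 1 more, which updated 1 symbol. Each of 18193 genes was represented by its brightest single-gene probe set, chosen without regard to group. Of the 298 called genes 160 had at least 2 tested probe sets, and for 55 of these another probe set was called in the same direction and for 0 in the opposite one. Of the 66 called genes named by the rule, 16 had another tested probe set that did not pass, and for 2 of these it had the opposite sign. A further 59 genes had a called probe set that was not the brightest.

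Groups were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets. All adjusted p-values of genes are from this limma fit unless another test is named. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over 28 lists. Of 471 list genes 342 were tested. Another 33 were not analysed here, since no single-gene probe set in use named them, and 96 were too dim. Control ratios were compared with exact permutation tests of 4 against 4 arrays, whose smallest two-sided p is 0.0286. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and plotted with matplotlib 3.10.9.

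The model was tested on simulated data with 200 of 27022 probe sets changed. It recovered 65% of those changed by 0.5 on the log2 scale and 100% of those changed by 1 or by 2, and 6.01% of its calls were unchanged probe sets. With no change simulated it made 1 call. The simulated noise was independent between probe sets, without array effects or correlation between genes, so rates on the real arrays can differ. On the real arrays, pairs of arrays correlated at 0.973 to 0.982 within groups and 0.964 to 0.979 between groups (Pearson's r across probe sets, which are not independent). The first principal component held 27.8% of the variance and set the groups apart, from -29.9 to -0.44 with retinoic acid alone and from 1.87 to 18.0 with the agonist. Replicate 4 of the retinoic acid group lay farthest out at -29.9. Replicate 3 of that group (-0.44) and replicate 7 of the agonist group (1.87) lay next to each other.

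The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule names the 15 largest rises and the 15 largest falls among called genes whose groups did not overlap, measured members of the lists, and Gli1. The alternatives were quantile normalization, centring each array on its median, adding 1 or 64 to the intensities, no filter or a filter at the 60th percentile, no intensity trend, array weights, the mean of a gene's probe sets, the hybridisation day as a block, an estimated correlation in the list tests, and leaving out each array. The second hybridisation day alone, and calls by any probe set of a gene, were added after seeing the data.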

Results

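Gene expression was measured in mouse embryoid bodies, the round aggregates that embryonic stem cells form when they differentiate in suspension. The stem cell line, given as YFP3.1 for 7 of the 8 samples, carries a constitutively expressed, FLAG-tagged form of Gli1, a transcription factor of the Hedgehog (Hh) pathway. Bodies were kept in suspension for 2 days and then received 500 nM retinoic acid, a vitamin A derivative that directs them to a neural fate of hindbrain and spinal cord character. A set of 4 samples received retinoic acid alone, and another 4 also received 1 uM of an Hh agonist, a compound that switches the Hh pathway on. For 7 of the 8 samples the labels place the collection at 3 days of differentiation, while for replicate 7 of the agonist group, grouped by its title, they give neither a time nor the line. The design describes the samples as biological replicates without saying how the cultures were separated, so the p-values measure the spread between these samples. Each sample was hybridised to 1 short-oligonucleotide array with 45101 probe sets. The median intensity per array lay between 21.6 and 22.6, and the number of arrays limits the precision.

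The comparison asks which transcripts differ when Hh signalling is switched on in neural embryoid bodies. With the agonist, genes of the ventral neural tube and of young neurons were higher, and Dbx1, Irx3 and Pax6, genes of more dorsal or intermediate progenitors, were lower. Nkx2-9, a homeobox gene of the most ventral progenitors, went from 2.28 ± 0.815 to 148 ± 22.9 (mean intensity ± SD, n = 4 per group). Foxa2, the transcription factor that specifies the floor plate at the ventral midline, went from 55.1 ± 1.48 to 398 ± 39.6. Isl1, a homeobox gene of motor neurons and other early neurons, went from 16.4 ± 2.30 to 117 ± 5.16. Dbx1, which marks progenitors in the middle of the dorsoventral axis, went from 169 ± 16.7 to 8.61 ± 4.06.

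In all, 506 of 27022 tested probe sets passed an adjusted p of 0.05 in limma, 308 of them higher and 198 lower with the agonist. Taking the brightest probe set of each gene, 298 of 13675 genes passed, with 179 higher and 119 lower. Lower genes outnumbered higher ones without retinoic acid replicate 3 (195 against 172) and without agonist replicate 7 (161 against 154). The 119 lower genes were 54 without retinoic acid replicate 2, 77 without replicate 4, 53 and 62 without agonist replicates 6 and 8, and 43 without an intensity trend in the model. The 4 values of each group did not overlap for 291 of these genes. Among all genes tested 8.02% had no overlap, against 2.86% given by chance. At least 2-fold changes were found for 44 genes, 36 higher and 8 lower. Fold changes were computed on log2(intensity + 16) and understate the change of dim genes, in particular where a group lies under the filter level of 15.1, so the count of 2-fold changes was 71 with 1 added in place of 16 and 17 with 64 added. The smallest change called was 0.15 on the log2 scale, and the median standard error over all genes was 0.11.

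**Figure D1:**
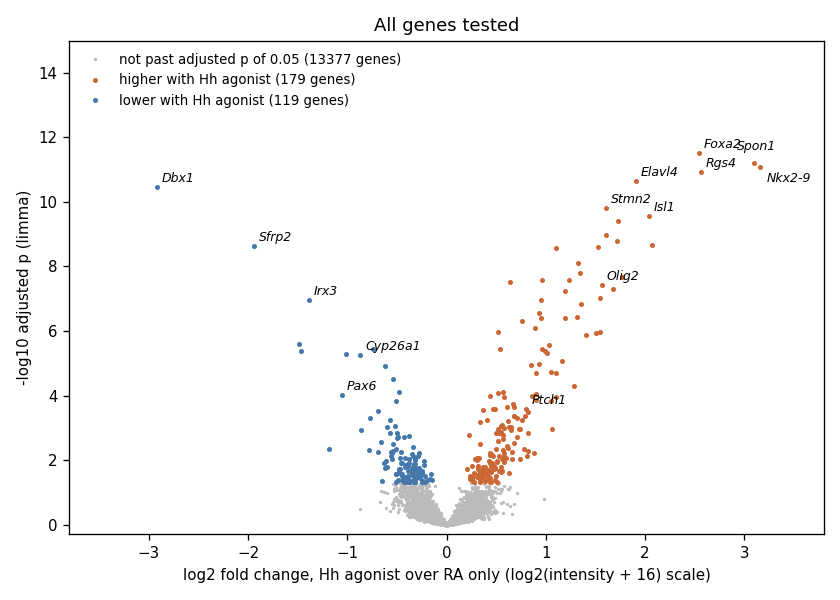
Each point is 1 of 13675 genes, with the log2 fold change of the agonist group over retinoic acid alone on the x axis and -log10 of the limma adjusted p on the y axis. Foxa2 had the lowest adjusted p (2.98e-12), and Nkx2-9 and Dbx1 had the largest changes upward (3.16) and downward (-2.92) on this scale, although with 64 added in place of 16 Foxa2 (1.95) lay above Nkx2-9 (1.67).

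Ventral progenitor genes rose as a group. Of 10 tested members 5 rose, none fell and 5 did not pass, with the same 5 passing when adjusted over the list alone. Nkx2-9 had a log2 fold change of 3.16 (SE 0.11, adjusted p = 8.14e-12), and Foxa2 one of 2.54 (SE 0.081, adjusted p = 2.98e-12). Nkx6-1, a homeobox gene shared by several ventral progenitor domains, rose from 13.5 ± 3.23 to 84.2 ± 9.64 (adjusted p = 2.08e-08). Olig2, which specifies motor neuron progenitors, rose 2.96-fold and its relative Olig1 rose from 14.5 ± 5.39 to 69.5 ± 6.60. Among members that did not pass, Shh, the Hh ligand made by the floor plate, had 35.1 ± 8.24 against 38.4 ± 8.26, and Foxa1 had 45.4 ± 6.81 against 45.1 ± 9.58. Nkx2-2 and Nkx6-2 were too dim to be tested, at 13.7 ± 2.10 and 15.6 ± 5.31 with the agonist. The list passed the camera set test (adjusted p = 4.78e-14, and adjusted p = 0.00168 with an estimated correlation).

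Floor plate genes also rose, with 5 of 10 tested members higher, none lower and the same 5 passing when adjusted over the list alone (camera adjusted p = 4.71e-15, and adjusted p = 0.00168 with an estimated correlation). Besides Foxa2 these were Spon1, which encodes the secreted protein F-spondin, Slit2 and Ntn1, which encode axon guidance proteins, and Vtn, which encodes vitronectin. Spon1 went from 3.73 ± 1.73 to 153 ± 14.2, a log2 fold change of 3.10 (SE 0.11). Another Spon1 probe set, brighter than that one with retinoic acid alone, had 27.0 ± 7.84 against 42.9 ± 7.68 (adjusted p = 0.121), and yet another had a log2 fold change of 0.24 (adjusted p = 0.666). Slit2 rose 3.28-fold, Vtn 2.15-fold and Ntn1 1.95-fold, each with a dimmer probe set that did not pass (log2 fold changes of 0.14, 0.27 and 0.34). The brightest probe set of Slit1 had a log2 fold change of 0.13 (adjusted p = 0.733), while a dimmer one went from 9.68 ± 3.02 to 44.9 ± 7.00 (adjusted p = 1.34e-05).

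**Figure D2:**
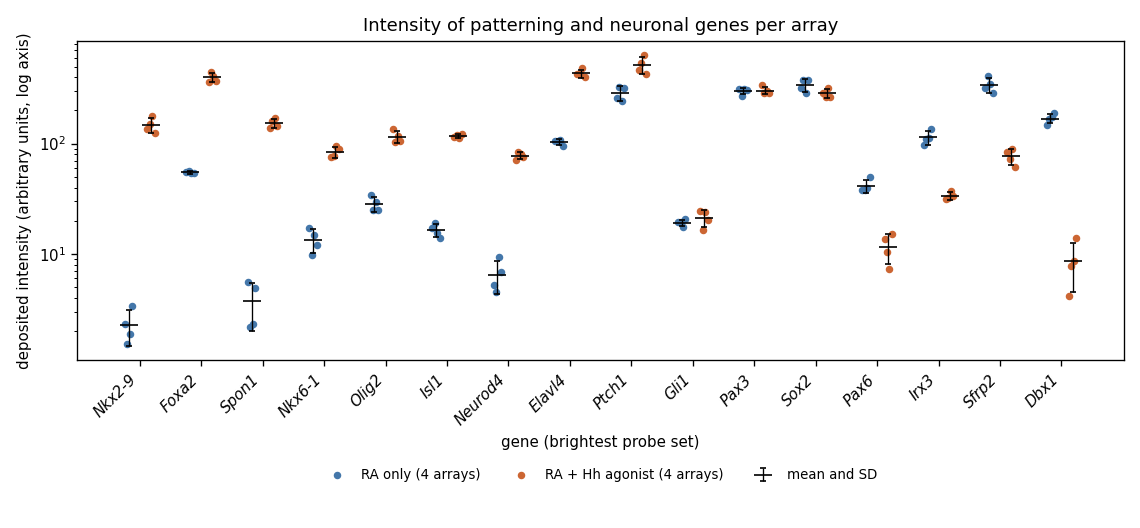
Deposited intensity (log axis) of 16 genes in the 4 arrays with retinoic acid alone and the 4 with the agonist as well, where points are arrays and bars are the mean and SD. Nkx2-9 averaged 2.28 without and 148 with the agonist, Dbx1 169 and 8.61, and the values of Gli1 (19.2 and 21.2) and Pax3 (302.5 and 302.9) overlapped.

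The list of dorsal and intermediate progenitor genes was shifted downward. Of 13 tested members 3 fell, none rose and 10 did not pass, while adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.000253). The list's adjusted p was 0.0307 with an estimated correlation. Dbx1 fell by 2.92 on the log2 scale (SE 0.12, adjusted p = 3.53e-11). Irx3, a homeobox gene kept out of ventral domains by Hh signalling, fell by 1.39 (SE 0.10, adjusted p = 1.07e-07), from 114 ± 15.8 to 33.5 ± 2.57. Pax6, a paired-box gene repressed at high Hh levels, fell by 1.06 (SE 0.13, adjusted p = 9.80e-05), from 41.3 ± 5.71 to 11.6 ± 3.58. Pax3, a gene of dorsal progenitors, had 302 ± 20.2 against 303 ± 23.4, and Msx1 had 47.0 ± 4.10 against 41.7 ± 3.82. None of 10 tested roof plate and dorsal signal genes passed (camera adjusted p = 0.373).

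Of the genes that the Hh pathway itself induces, Ptch1, the Hh receptor, rose 1.75-fold, from 288 ± 43.7 to 515 ± 91.2 (adjusted p = 0.000253). Hhip, an Hh-binding inhibitor, had 21.2 ± 12.7 against 34.2 ± 9.64 (adjusted p = 0.367). Gli1 was dim in both groups, with 19.2 ± 1.24 against 21.2 ± 3.72 (adjusted p = 0.874), and whether its probe set detects the tagged Gli1 transcript was not examined. The list of feedback genes thus had 1 of 3 tested members higher, also when adjusted over the list alone (camera adjusted p = 0.00410). Its adjusted p was 0.147 with an estimated correlation. None of 17 receptors and transducers passed by its brightest probe set (camera adjusted p = 0.711), and their median (0.035) and mean (-0.0040) change had opposite signs. A dimmer probe set of Gli3, a transcriptional repressor of the pathway, went from 45.1 ± 1.98 to 12.3 ± 1.19 (adjusted p = 6.63e-06), while its brightest one had a log2 fold change of -0.076 (adjusted p = 0.836). Gas1, an Hh co-receptor, likewise had a dimmer probe set that went from 26.5 ± 3.89 to 10.4 ± 2.45 (adjusted p = 0.00940).

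Pan-neuronal genes gave the lowest camera p of the 28 lists. Of 18 tested members 11 rose, none fell and 7 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 1.52e-30). The list's adjusted p was 0.000878 with an estimated correlation. Elavl4, a neuronal RNA-binding protein gene, went from 103 ± 5.88 to 433 ± 35.9, a log2 fold change of 1.91 (SE 0.076, adjusted p = 2.21e-11). Neurod4, a proneural transcription factor gene, rose from 6.49 ± 2.13 to 78.0 ± 5.74, a log2 fold change of 2.07 that was 3.44 with 1 added in place of 16 and 1.01 with 64. The neurofilament genes Nefm and Nefl rose 3.05-fold and 2.87-fold, Stmn2 rose 3.05-fold, Gap43, a growth cone gene, 2.28-fold, and Tubb3, the neuronal beta-tubulin, 1.99-fold. Elavl3 rose 1.41-fold (adjusted p = 0.0413), a call lost in 12 of the 19 other settings. The brightest probe sets of Dcx and Mapt did not pass (adjusted p = 0.974 and 0.952), while a dimmer one of each did (0.0225 and 0.000919).

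Among motor neuron genes 2 of 8 tested rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.000126, and adjusted p = 0.0307 with an estimated correlation). The genes that rose were Isl1, with a log2 fold change of 2.04 (SE 0.097, adjusted p = 2.81e-10), and Neurog2, a proneural gene of motor neuron progenitors and other neurons, with 0.93 (SE 0.097, adjusted p = 1.07e-05). Lhx3 had 30.8 ± 2.51 against 33.0 ± 2.08, Mnx1 18.6 ± 4.32 against 18.1 ± 4.08 and Isl2 113 ± 4.05 against 111 ± 5.59. Another 6 members were too dim to be tested. Of these, Ret alone passed when tested without the filter, from 5.97 ± 2.21 to 26.2 ± 6.95 (limma adjusted p = 0.00120). Isl1 was also the 1 dorsal interneuron gene of 8 that rose (camera adjusted p = 0.0985), and none of 9 ventral interneuron genes passed (camera adjusted p = 0.525).

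Of 16 neural progenitor genes 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00209). The list's adjusted p was 0.208 with an estimated correlation, and 2 genes rose without retinoic acid replicate 1 or agonist replicate 6 or 7. Hey1, a Notch target, rose 2.49-fold and Fabp7, a radial glia gene, 1.66-fold, while Sox2 had 340 ± 44.9 against 285 ± 26.9 (adjusted p = 0.254) and Nes 262 ± 26.7 against 268 ± 5.09 (adjusted p = 0.885). In the list of oligodendrocyte and astrocyte genes Olig1 rose and the other 10 did not pass (camera adjusted p = 0.386).

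**Figure D3:**
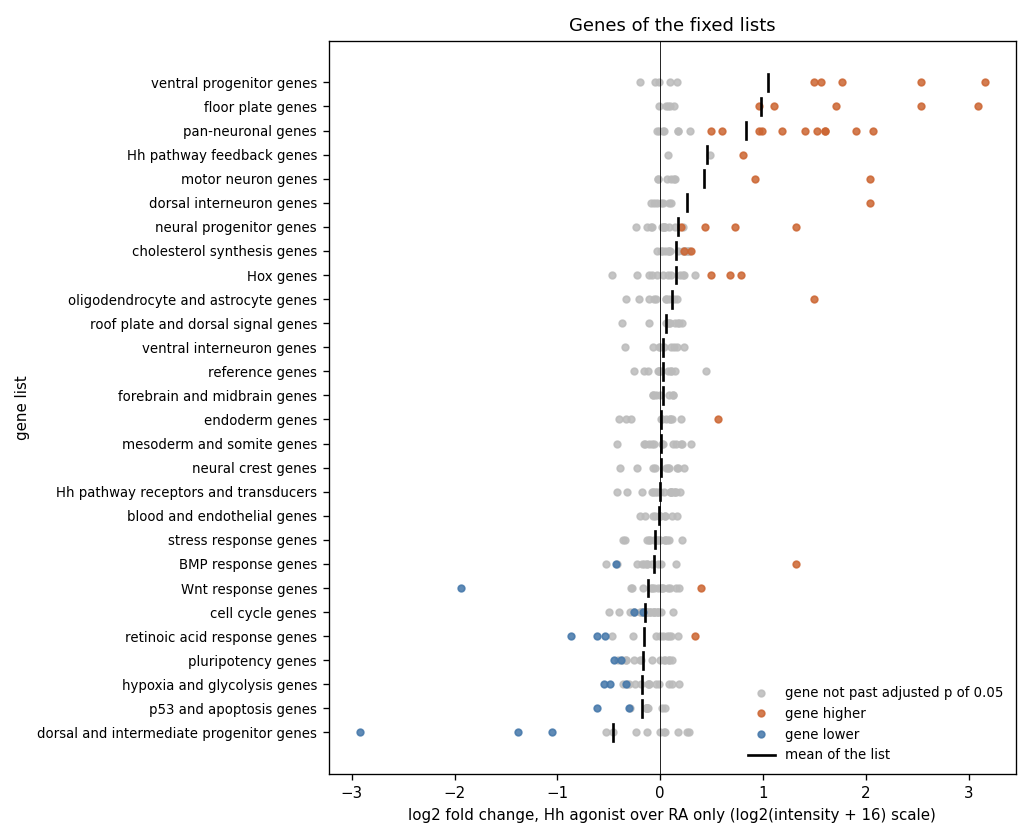
Log2 fold change (x axis) of every tested gene of the 28 fixed lists (rows), with genes that passed in colour, other genes in grey and the mean of each list as a black line. The mean was 1.05 for ventral progenitor, 0.98 for floor plate, 0.83 for pan-neuronal and -0.45 for dorsal and intermediate progenitor genes.

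Genes of the retinoic acid response list moved both ways. Of 13 tested members 3 fell and 1 rose, with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0186). The list's adjusted p was 0.275 with an estimated correlation, and its median change was -0.0054 against a mean of -0.15. Cyp26a1, the enzyme that degrades retinoic acid, fell by 0.87 on the log2 scale (SE 0.086, adjusted p = 5.49e-06). Crabp2, a retinoic acid carrier, fell by 0.62 and Stra8, a retinoic acid target of germ cells, by 0.54, while Crabp1 rose 1.26-fold (adjusted p = 0.0327), a call lost without any 1 of retinoic acid replicates 1, 2 and 3 or agonist replicates 6, 7 and 8. Rarb, a retinoic acid receptor gene, had 21.8 ± 2.09 against 20.8 ± 2.66. Of 15 tested Hox genes, which set position along the head-to-tail axis, 3 rose and none fell, while 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00634). The adjusted p of the Hox list was 0.147 with an estimated correlation. Hoxb5 rose 1.73-fold, Hoxb4 1.61-fold and Hoxd3 1.41-fold. Hoxb1, an early retinoic acid target and the gene lower over the list alone, had 43.9 ± 10.8 against 27.6 ± 9.37, a log2 fold change of -0.47 (adjusted p = 0.195 over all probe sets tested). Hoxb5os, annotated as an opposite-strand transcript of Hoxb5, was 2.77-fold lower (adjusted p = 4.20e-06).

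Smaller shifts were found in 5 lists of general cell state, and none of these calls held when the correlation between genes was estimated. Of 28 cell cycle genes Ccna2 and Pcna fell, with 7 lower adjusted over the list alone (camera adjusted p = 1.33e-06, and adjusted p = 0.256 with an estimated correlation). Of 16 pluripotency genes Klf2 and Dppa4 fell, with 5 lower adjusted over the list alone (camera adjusted p = 0.00184, and adjusted p = 0.383 with an estimated correlation). Nanog had 121 ± 39.6 against 87.0 ± 7.75 and Pou5f1 141 ± 42.3 against 113 ± 19.1. Without retinoic acid replicate 3, whose mean over the pluripotency list (7.22 on the log2 scale) lay below all agonist arrays (7.26 to 7.35), 7 of these genes fell. None fell without retinoic acid replicate 1 or agonist replicate 6, 1 fell without retinoic acid replicate 2 or 4 or agonist replicate 5 or 8, and the list's mean change of -0.16 was -0.10 without retinoic acid replicate 4. The 2 cell cycle calls were 4 without retinoic acid replicate 3 or agonist replicate 7 and 0 without retinoic acid replicate 1 or 2 or agonist replicate 5, 6 or 8. Of 16 hypoxia and glycolysis genes the glucose transporters Slc2a1 and Slc2a3 and the stress gene Ddit4 fell, with 6 lower adjusted over the list alone (camera adjusted p = 0.000639, and adjusted p = 0.298 with an estimated correlation). Of 11 p53 and apoptosis genes Ccng1 and Perp fell, also adjusted over the list alone (camera adjusted p = 0.00184, and adjusted p = 0.266 with an estimated correlation). The p53 list had 0 lower genes without retinoic acid replicate 2 or agonist replicate 6 or 8, and 1 without retinoic acid replicate 4. Of 16 cholesterol synthesis genes Hmgcs1 and Msmo1 rose, with 7 higher adjusted over the list alone (camera adjusted p = 3.35e-06, and adjusted p = 0.143 with an estimated correlation), and 1 rose without retinoic acid replicate 2 or agonist replicate 7 or 8. With quantile normalization 5 cholesterol genes rose, and 0 did without an intensity trend, with the mean of a gene's probe sets or on the second day alone. Without an intensity trend 0 pluripotency, cell cycle and p53 genes and 1 hypoxia and glycolysis gene fell. The groups also overlapped in the array means of the other lists that fell here. Retinoic acid replicate 3 lay below agonist replicate 7 for cell cycle (8.31 and 8.40), hypoxia and glycolysis (8.36 and 8.43) and p53 genes (6.86 and 6.89). The cholesterol means did not overlap (7.60 to 7.72 against 7.76 to 7.92). Whether the falling lists moved separately or together was not tested.

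Of 16 Wnt response genes Sfrp2, a secreted Wnt modulator, was 3.83-fold lower and its relative Sfrp1 rose 1.32-fold (camera adjusted p = 0.547 for the list). Of 13 BMP response genes Id3 fell by 0.43 on the log2 scale and Hey1 rose, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.113). With quantile normalization 3 BMP response genes fell, and 2 did with arrays centred on their median. Markers of other cell types mostly did not pass. None of 10 neural crest, 13 mesoderm and somite, 11 blood and endothelial or 7 forebrain and midbrain genes passed, and the camera adjusted p of these lists was 0.644, 0.711, 0.989 and 0.711. For the blood and endothelial list the test's direction was upward while its median and mean change lay slightly below 0. Of 11 endoderm genes the collagen gene Col4a1 rose 1.48-fold (camera adjusted p = 0.671 for the list). None of 15 stress response genes and none of 12 reference genes passed (camera adjusted p = 0.570 and 0.528).

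The remaining genes among the 15 largest rises were Rgs4, a regulator of G-protein signalling (5.91-fold), Olfml3 (3.31-fold), Arg1, the arginase gene (3.19-fold), and Chgb, a protein of secretory granules (2.93-fold). Among the 15 largest falls were also Ndnf (47.1 ± 4.44 to 6.72 ± 3.51), the axon guidance gene Sema3e (2.28-fold lower by its brightest probe set), the gap junction gene Gja1 (2.01-fold), Rec8, a meiotic cohesin gene (1.82-fold), Moxd1 (26.6 ± 5.91 to 8.62 ± 2.10), Zfp41 (1.71-fold), Cpm (1.67-fold), the carbonic anhydrase gene Car2 (1.62-fold) and Tagln, an actin-binding protein gene of smooth muscle (1.61-fold). A dimmer Rgs4 probe set was called too, from 7.55 ± 2.77 to 58.1 ± 9.61, while another, brighter with retinoic acid alone, had 60.3 ± 10.4 against 74.0 ± 10.7 (adjusted p = 0.409). The other tested Sema3e probe sets had log2 fold changes of 0.061 and 0.065 (adjusted p = 0.935 and 0.898), and its call was lost with the mean of its probe sets (adjusted p = 0.532) and without an intensity trend (0.0536), within a range of 0.000490 to 0.532 over the settings.

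Of the 28 lists, 14 passed the camera test with a preset correlation, 8 upward and 6 downward. The calls of 5 lists held with an estimated correlation, namely pan-neuronal, ventral progenitor, floor plate, motor neuron and dorsal and intermediate progenitor genes. With fry, which tests whether the genes of a list move one way on balance and does not compare the list with other genes, 11 lists passed. Of those called by camera, the cell cycle (fry adjusted p = 0.0999), pluripotency (0.187), p53 and apoptosis (0.0871) and hypoxia and glycolysis (0.0871) lists did not pass fry. The dorsal interneuron list passed fry (adjusted p = 0.000862) but not camera.

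The arrays were processed on 2 days, replicate 1 of the retinoic acid group and replicate 5 of the agonist group on the first and the other 6 on the second, where each group had a fluidics station of its own. With the day as a block, which cannot move a fold change since each day held as many arrays of both groups, 537 probe sets passed, and 191 genes were higher and 128 lower. The second day alone, 3 against 3 arrays, gave 266 probe sets, 109 genes higher and 48 lower, and the first day's 1 array per group allowed no test. The mean shift of the pan-neuronal list was 0.82 within the first day and 0.84 within the second, that of the ventral progenitor list 1.04 and 1.06, and that of the dorsal and intermediate progenitor list -0.43 and -0.46. The days differed more for the Hh feedback list, at 0.72 and 0.36, and for the Hox list, at 0.23 and 0.12. The feedback list has 3 tested genes, and its Ptch1 changed by 0.80 on both days. Hhip was 4.73 in retinoic acid replicate 1, on the first day, against 19.9 to 35.2 in the other retinoic acid arrays. The difference between days of that list thus leans on 1 dim value. RNA integrity, read from the Actb 3' to 5' ratio, was 1.45 ± 0.0587 without and 1.47 ± 0.0547 with the agonist (n = 4 per group, exact permutation p = 0.743, adjusted p = 0.743 over 4 control measures, two-sided). The lowest p of the 4 measures was that of the hybridisation spikes, added control transcripts. Their mean log2 intensity was 8.31 ± 0.0574 without and 8.39 ± 0.0361 with the agonist (exact permutation p = 0.0857, adjusted p = 0.343).

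**Figure D4:**
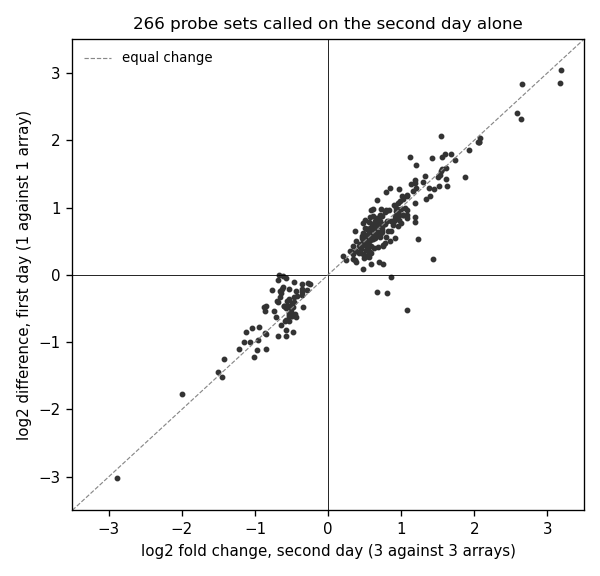
Log2 fold change on the second day (x axis, 3 against 3 arrays) and log2 difference of the first-day pair (y axis, 1 against 1 array) for the 266 probe sets called on the second day alone, with the dashed line marking equal change. Of these, 261 had the same sign on both days.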

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

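Of the tests here, only the count over splits of the arrays was chosen before its result was seen. The tests of station, progenitor share, intensity and retinoic acid exposure were chosen after.

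The first pattern is the set of 506 called probe sets. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many, the real one, and the highest of the others gave 1. This argues against chance but cannot exclude it, since 1 of 35 is the lowest share the count can reach. The splits also did not keep the hybridisation days apart. On the second day the fluidics station coincided with the group. Of 266 probe sets called on that day alone, 98.1% had the same sign in the first-day pair, which shared 1 station. The exact 95% interval was 95.7 to 99.4%, against 50.4% of probe sets of like intensity picked for showing little difference on the second day. Their signs were bound to split about evenly, so the 50.4% is not a fair baseline. Both shares were read from 1 pair of arrays, and some called probe sets name the same gene. The interval therefore does not measure the spread between arrays. As far as 1 pair can show, the shared signs argue against the station. The hybridisation day was not tested as a cause, since each day held as many arrays of both groups. An effect of the agonist, the difference the design names, remains as a hypothesis.

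The second pattern is the rise of pan-neuronal genes, with a mean log2 change of 0.83. If progenitor and neuronal classes had been raised alike by a lower share of undifferentiated cells, both lists would have moved together. The neuronal mean rose over the mean of 16 progenitor genes (0.17) by 0.66 (SE 0.034). Both list means were known when this test was chosen, so it shows only that the lists did not rise alike. It cannot decide about a lower share that raises the classes unequally. Pluripotency genes had a mean change of -0.16, with 2 lower and 0 higher (camera adjusted p = 0.00184, and adjusted p = 0.383 with an estimated correlation). They did not follow the neuronal rise array by array. Retinoic acid replicate 3 had the lowest pluripotency mean of all arrays (7.22, against 7.26 to 7.35 with the agonist). Its pan-neuronal mean was 6.32, against 7.10 to 7.16 with the agonist. The lower pluripotency genes numbered 0 to 7 when 1 array was left out. A lower share of undifferentiated cells stays open as a part of the rise, but not as one that raises progenitor and neuronal genes alike. Genes of like intensity did not rise as much, since the highest mean of 10000 random sets of them was 0.32 against 0.83. This argues against a general shift of dim probe sets, although the neuronal rise was known when the test was chosen. The random sets ignored correlation between genes, so their range can be too narrow. More or earlier neurons with the agonist, or higher expression per neuron, stay open and cannot be separated in RNA from whole bodies.

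The third pattern is that Cyp26a1, Crabp2 and Stra8 fell while Hoxb4, Hoxb5 and Hoxd3 rose. Lower exposure to retinoic acid would lower Hox genes of paralog groups 1 to 5, and the mean change of the 10 tested ones was 0.19 (SE 0.047). That mean rests on the 3 called genes, which are part of the pattern, and the other 7 averaged -0.0022 (SE 0.056), with Hoxb1, an early retinoic acid target, at -0.47 (adjusted p = 0.195). Of the 13 tested genes of the retinoic acid response list 3 fell and 1, Crabp1, rose, and the median change was -0.0054. Lower exposure and a different mix of cell types with the agonist therefore both stay open, the first undecided by these values and the second not tested.

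Of 218 groups of 4 arrays, over 109 named genes, 10 held a value set apart from the other 3 by Dixon's criterion, against 10.9 given by chance. In the retinoic acid group they were Hey1 in replicate 1 (32.8, against 47.8 to 49.5 in the other arrays), Elavl4 in replicate 4 (94.8, against 106 to 108) and Pax6 in replicate 4 (49.8, against 37.7 to 39.4). In the agonist group replicate 5 had a low Axin2 (15.5, against 30.2 to 32.7). Replicate 6 had a high Lhx3 (36.1, against 31.9 to 32.0), a low Pcna (1362, against 1408 to 1415) and a low Sfrp1 (103, against 128 to 130.0). Replicate 8 had a high Slit1 (56.3, against 34.7 to 36.9), a low Sox10 (43.3, against 61.4 to 65.0) and a high Stmn2 (736, against 682 to 689). Among 64 control probe sets outside the main comparison, AFFX-r2-P1-cre-3 averaged 3115 with and 2907 without the agonist, and AFFX-TrpnX-5 averaged 11.9 and 7.20. AFFX-MURINE_b1 was separated the other way, at 965 with and 1127 without the agonist. All 3 had an exact permutation p of 0.0286, the smallest possible, against 1.83 separated sets given by chance, and the lowest adjusted p was 0.610.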

How the results depend on the processing

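The second hybridisation day alone and calls by any probe set were chosen after seeing the data. Of the 66 called named genes, 61 were tested under all 19 other settings and 41 of these passed under all of them. Hoxb5, Moxd1, Ndnf, Neurod4 and Pax6 were not tested under 1 to 3 settings and passed wherever tested, and the Hh feedback list was tested under all but the filter at the 60th percentile and the mean of probe sets. Where tested, no called named gene or list changed direction. The calls lost most often were Elavl3 (12 settings), Pcna (10), and Ccna2, Crabp1, Dll3 and Klf2 (9 each), and in all 114 of the named-gene results lost their call and 11 gained one. Without an intensity trend 264 probe sets, 115 higher and 43 lower genes passed, and on the second day alone, with fewer arrays, 266, 109 and 48, and the cause of the change without a trend was not tested. At least 2-fold changes numbered 71 with 1 added and 17 with 64 added, since a larger constant shrinks the folds of dim genes. With an estimated correlation 5 lists passed. Leaving out 1 array gave 298 to 615 probe sets, 132 to 176 higher and 53 to 195 lower genes, 41 to 45 genes changed at least 2-fold, and 14 to 15 lists. Called probe sets numbered 324 without retinoic acid replicate 2 and 298 without agonist replicate 6. Lower genes numbered 54, 195 and 77 without retinoic acid replicates 2, 3 and 4, and 53 and 62 without agonist replicates 6 and 8, and the cause was not tested. Higher genes no longer outnumbered lower ones without retinoic acid replicate 3 (172 and 195) or agonist replicate 7 (154 and 161), and centring on the median gave 163 and 149. Without the filter the Hox list did not pass (adjusted p = 0.142), nor did the retinoic acid response list without an intensity trend (0.0597). With a filter at the 60th percentile the dorsal interneuron (0.0435) and the oligodendrocyte and astrocyte (0.0329) lists passed, the former also without retinoic acid replicate 2 (0.0319). On the second day alone 0 pluripotency and cell cycle genes fell, and 2 neural progenitor genes rose there and without an intensity trend. Of cell cycle genes 1 fell with quantile normalization or no filter. Calls by any probe set gave 208 higher and 149 lower genes. Signal over background limits the dim genes. Of 96 list genes under the filter, Ret of the motor neuron list alone passed when tested (log2 fold change 0.93, adjusted p = 0.00120). No paired analysis was possible because the sample numbers 1 to 8 are not shared between the groups.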

Other observations

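The genes named here were chosen after their values were seen, and both tests were chosen after the list of called genes had been seen.

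Several called genes outside the fixed lists, picked by hand and not tested as a group, were higher with the agonist. Phox2a, a homeobox gene of hindbrain visceral motor and noradrenergic neurons, went from 9.09 ± 3.89 to 45.1 ± 9.79 (mean intensity ± SD, n = 4 per group), a log2 fold change of 1.28 (SE 0.15, limma adjusted p = 4.94e-05). Insm1, a zinc-finger gene of newborn neurons and endocrine cells, rose 2.07-fold, and the granule genes Scg3 and Chga rose 2.24-fold and 1.46-fold. Ddc, an enzyme of monoamine synthesis, rose 1.94-fold from 95.2 ± 6.12 to 199 ± 8.67. The axon guidance receptor gene Robo2 rose 2.53-fold, the adhesion gene Ncam1 2.35-fold, Ebf1 2.08-fold, Ebf3 1.61-fold and the kinesin genes Kif5a and Kif5c 1.82-fold and 1.69-fold. Sulf1, a heparan sulfate sulfatase gene, rose 2.56-fold and Rfx4, a regulator of cilia and neural tube genes, 2.08-fold.

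Others, also picked by hand, were lower by smaller amounts. Krt8 and Krt18, the keratins of simple epithelia, were 1.32-fold and 1.30-fold lower, and Cldn4, a tight junction gene, was 1.37-fold lower. Myl9, a myosin light chain gene, was 1.51-fold lower, Anxa2 1.49-fold, Anxa3 1.46-fold and Vcl, the vinculin gene, 1.27-fold. The metallothionein genes Mt1 and Mt2 were 1.17-fold and 1.26-fold lower.

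A candidate explanation for the falls of Krt8, Krt18 and Cldn4 is a shared fall of epithelial genes, tested on 22 other such genes, none of them called. The 20 tested had a mean log2 change of -0.14 (SE 0.055), 15 were below 0, and the exact permutation p of the 4 against 4 array means was 0.0571 (adjusted p = 0.114 over 2 tests), so the hypothesis stays open. Stra8, Rec8 and Syce2, genes of meiotic prophase, fell by 0.54, 0.86 and 0.29 on the log2 scale, and a shared fall of meiotic genes was tested on 24 others, also without called genes. The 14 tested averaged -0.085 (SE 0.058), 9 were below 0, and the exact permutation p was 0.286 (adjusted p = 0.286), which decides neither way. Both lists left out called genes by construction, so neither result excludes a shared fall.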
